A study of Homo sapiens with 3 samples.

How the data were processed

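RNA sequencing was done on 3 libraries labelled as undifferentiated pleomorphic sarcoma (UPS), a malignant soft tissue tumour with no recognisable line of differentiation. The samples carried the label of no treatment. Per the labels' protocols, tissue was homogenised mechanically, total RNA was purified on columns, polyadenylated RNA was turned into stranded libraries and reads of 75 nt were taken from one end on a NextSeq 500. The labels do not say whether the 3 libraries came from separate tumours, and the series' design text speaks of a tumour in the singular.

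The authors deposited a ranked gene list, and values per library were not used here. Its score, per the file headers, is the sign of the authors' log fold change multiplied by -log10 of the authors' unadjusted p-value. Per the submitters' processing notes, TopHat2, RSEM and edgeR were used with genome build hg19, and per the file name the test was an edgeR generalised linear model on RSEM expected counts. A script call in the file header carries a setting of 0.25, whose effect is not explained there. The recovered p-values ran up to nearly 1 (largest 0.9998), so no p-value limit had been applied to the rows. Tool versions, the gene annotation, whether counting used strand, any filter on low counts, library sizes, and the groups and number of libraries on each side of the contrast are not given in the sources used here. The direction of every result is therefore the sign in the table (positive or negative). Depth is unknown, and no fold change, standard error or mean ± SD could be given. A score mixes the size of a difference with its precision, so long or abundant genes can reach larger scores than short or rare ones at the same fold change.

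Each p-value was recovered as 10 to the power of minus the absolute score and adjusted over all 17989 genes by the Benjamini-Hochberg method, with a threshold of 0.05. Symbols were used as the table gives them, and no symbol occurred more than once. Since the reference used here is of another build than hg19, no coordinates are given. It served for names (17825 symbols matched, 99.1%) and for the GC content and length of the longest GENCODE release 29 transcript (17742 genes, 98.6%). For privacy, 24 sex-linked genes were counted in the totals but are not reported singly.

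Before the data were examined, 39 gene lists (5 on the pathways named in the series title and on super-enhancer cofactors, 20 on cell programmes and 14 of cell type markers), the rule for named genes and the alternative settings were fixed. Of 892 list places, 852 had a gene in the table. The list of 18 replication-dependent histone genes and 13 of 20 cancer-testis antigens were not analysed here, which left 38 lists with at least 5 members. Each list was tested against all other genes with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on the ranks of the scores, with the correlation between genes preset at 0.01, and adjusted over the 38 lists. The correlation cannot be estimated from a ranked list, so presets of 0.05 and 0.1 were tried instead. Member counts were adjusted over all genes and, separately, over the list alone.

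Named genes were the 10 with the largest positive and the 10 with the largest negative score, the 3 members of each list with the largest absolute score and the farthest member of opposite sign past the threshold, and 15 genes fixed in advance, with YAP1, WWTR1, TEAD1, RELA, NFKB1, USP31, CTGF, CYR61, FOXM1, MYC, CDKN2A, MDM2 and RB1 among them. REL, TNFAIP3, CYLD, TEAD2, TEAD3 and TEAD4 were added after their values were seen. The text names part of the fixed set, and some genes and 1 list are not reported here.

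The alternative settings were other thresholds and adjustments, signed z-values, pre-ranked GSEA with fgsea 1.28.0, the percentile of each list's median among 10000 random lists of the same size, and lists without shared genes, without their most extreme member or without non-coding and uncharacterised names. A regression of the signed z-value on GC content and transcript length (natural splines with 5 degrees of freedom each), followed by the same list test on the residuals, was added after seeing the data. The list test was tested on simulated scores over the 17989 genes in 50 repeats. A shift of 1 SD was recovered in 98% of repeats in both lists that carried it, and a shift of 0.5 SD in 30% and 48%. Among lists with no shift, 0.516% were called. The simulated scores were drawn independently for each gene, so these shares do not show how the test behaves with correlated genes. Leaving out a library, pairing libraries and regrouping them were not possible without values per library.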

Results

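The data were the result of one differential expression test, given as a signed score for each of 17989 genes, in a study of 3 UPS tumour libraries. The title of the series names super-enhancers, the transcriptional co-activator YAP1 and the inflammatory transcription factor NF-κB, and the question put to the table was which genes and gene programmes stood on which side of the authors' contrast. The labels name neither side of the contrast and put all 3 libraries in one group. A positive score means a positive log fold change as the authors coded it. The table holds no replicate values, so each score stands without an error of its own, and the replicate spread enters only through the authors' p-value. Whether that spread is between tumours or within a single tumour is not known from the labels.

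Most of the measured transcriptome differed between the sides. After Benjamini-Hochberg adjustment of the authors' edgeR p-values, 13510 of 17989 genes (75.1%) passed 0.05, of which 7176 were positive and 6334 negative. The 10 genes at the positive end in the authors' deposited table were LTB (9.98), FOSL1 (9.90), IL2RB (9.79), ARHGEF1 (9.73), MFSD12 (9.73), CYBA (9.72), UBD (9.69), PLTP (9.62), IFI30 (9.61) and VASN (9.52). Among these, LTB is a cytokine of the TNF family, FOSL1 an AP-1 transcription factor, IL2RB a chain of the interleukin-2 receptor, CYBA a subunit of the phagocyte NADPH oxidase and IFI30 a lysosomal reductase of antigen processing. Among the genes at the negative end, the authors' deposited table held TECRL (-10.47), SNAP25-AS1 (-10.31), ACTN2 (-10.24), HHATL (-10.17), ASMT (-10.07), MYPN (-10.01), UNC45B (-9.97), ZBTB20 (-9.94) and KLHL31 (-9.93). ACTN2 and MYPN are proteins of the sarcomeric Z-disc, and UNC45B is a chaperone of muscle myosin. The adjusted p of these genes lay between 1.33e-07 and 1.41e-07. SNAP25-AS1 is an antisense gene, and its value is uncertain because the sources used here do not say whether counting used strand. An absolute score of 1.43 marked the threshold.

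**Figure D1:**
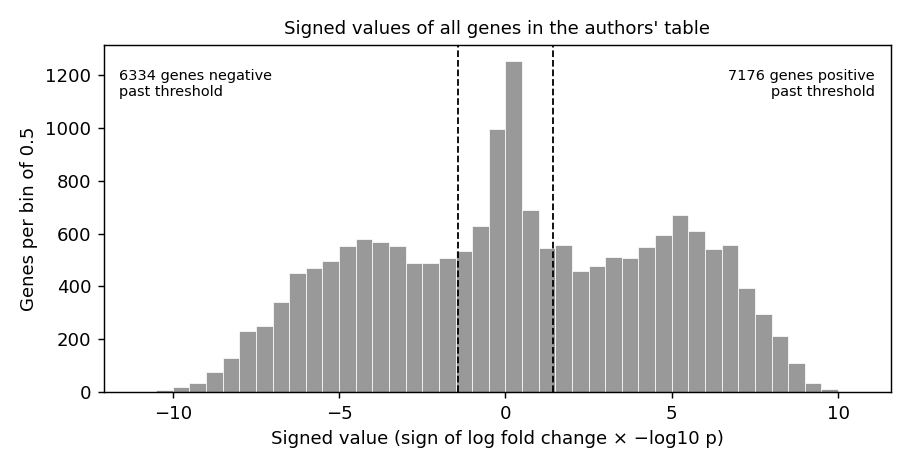
Histogram of the signed values of all 17989 genes. The x axis is the sign of the log fold change times −log10 p, the y axis the number of genes per bin of 0.5, and the dashed lines mark the adjusted threshold at an absolute value of 1.43. The 6334 negative and 7176 positive genes past the threshold form broad shoulders on both sides of a narrow peak near 0.

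Of the 38 gene lists, 21 were called against all other genes by cameraPR (adjusted p under the threshold), 15 toward the positive and 6 toward the negative side. In total 741 of 852 list places held a gene past the threshold, and 740 when adjusted over the list alone. Because 75.1% of all genes passed, a high count of members past the threshold is not by itself evidence for a list, and the direction of members and the competitive test carry the comparison.

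Skeletal muscle genes stood together at the negative end. All 34 genes of the contractile apparatus and its energy supply were negative and past the threshold, with a median of -7.96 (cameraPR, adjusted p = 4.60e-15). The most extreme in the authors' deposited table were ACTN2 (-10.24), TCAP (-9.75), a titin-capping protein of the Z-disc, and TNNT1 (-8.93), the troponin T of slow fibres. Of 20 myogenic regulators and developmental muscle genes, 19 were negative and 1 positive (median -6.17, adjusted p = 1.47e-07). They were led by EYA4 (-9.87), MYF6 (-9.60) and SIX4 (-8.52) in the authors' deposited table, with MEF2D (1.51) as the positive member. MYF6 is a myogenic basic helix-loop-helix factor, and EYA4 and SIX4 belong to the SIX-EYA network of muscle development. Counts adjusted over the list alone were identical for both lists.

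Genes of mitochondrial energy metabolism were also mostly negative. Of 33 oxidative phosphorylation genes, 27 were negative and 1 positive (median -3.14, adjusted p = 6.50e-04). Of 25 genes of the citric acid cycle and fatty acid oxidation, 20 were negative and 1 positive (median -3.03, adjusted p = 7.50e-04). Examples in the authors' deposited table were NDUFS1 (-6.09) of respiratory complex I, the medium-chain acyl-CoA dehydrogenase ACADM (-7.05) and HADHB (-6.40). The positive members were COX4I1 (2.21) and ETFB (5.16) in the authors' deposited table. With the correlation between genes preset at 0.1, neither list was called (adjusted p = 0.0858 and 0.0683). Erythroid genes were negative in 8 of 11 cases and positive in none (median -4.43, adjusted p = 4.65e-03, or 0.0641 with the preset at 0.1). They included SLC4A1 (-6.35), HBB (-5.89) and HBA2 (-5.63) in the authors' deposited table, and HBA2 shares reads with its near-identical copy HBA1.

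Immune genes formed the positive counterpart. All 22 genes of antigen presentation were positive and past the threshold (median 8.20, adjusted p = 2.54e-11), among them PSMB8 (9.08), an immunoproteasome subunit, HLA-DQA1 (8.90) and the peptide transporter TAP1 (8.82) in the authors' deposited table. HLA genes are polymorphic and similar to one another, so their single values are uncertain. All 24 T and NK cell markers (median 7.74, adjusted p = 1.36e-10) and all 24 macrophage and myeloid markers (median 7.01, adjusted p = 5.33e-10) were positive. The leading ones in the authors' deposited table were CD4 (9.21), CD2 (9.04) and NKG7 (8.87) for the lymphoid list, and AIF1 (8.98), MS4A4A (8.88) and TYROBP (8.23) for the myeloid list. Interferon response genes were positive in 24 of 25 cases, with 1 not past the threshold (median 7.67, adjusted p = 3.65e-10). ISG15 (9.28), IFIT2 (8.57) and IFIT3 (8.31) led that list in the authors' deposited table. Of 16 B and plasma cell markers, 15 were positive and 1 negative (median 5.65, adjusted p = 1.94e-04), with the B cell antigen MS4A1 at 8.90 and POU2AF1 at -4.37 in the authors' deposited table. Endothelial markers were positive in 17 of 20 cases and negative in 2 (median 5.71, adjusted p = 6.46e-05), from ENG (8.05) and SOX18 (7.90) to LYVE1 (-1.80) in the authors' deposited table. Counts adjusted over the list alone did not differ for these 6 lists.

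Among the genes the series title points to, NF-κB target genes were positive as a group and YAP targets were divided. Of 30 NF-κB targets, 28 were positive and 2 did not pass the threshold, with the same counts adjusted over the list alone (median 5.88, adjusted p = 8.89e-08). Of these targets, 4 also belong to the pathway list below and 1 to the immediate early list. The leading members in the authors' deposited table were NFKB2 (9.25), RELB (8.97) and the adhesion molecule ICAM1 (8.50). In the same table the list of 27 immediate early and stress genes was positive throughout (median 6.05, adjusted p = 1.47e-07), as were the leukocyte markers above. With the preset at 0.1, the NF-κB target and immediate early lists stayed called (cameraPR, adjusted p = 4.55e-03 for both). Of 22 members of the NF-κB signalling pathway itself, 13 were positive and 7 negative (median 5.39), and the list was not called (adjusted p = 0.0773). It was called by pre-ranked GSEA and against random lists. The list stayed uncalled without genes shared between lists (cameraPR, adjusted p = 0.386) and with GC content and length regressed out (cameraPR, adjusted p = 0.151). The subunits RELA (6.70) and NFKB1 (6.92) were positive and REL (-5.51) negative in the authors' deposited table. Deubiquitinases of the pathway went both ways in the authors' deposited table, with USP31 (-5.86), OTUD7B (-7.54) and CYLD (-2.72) negative and TNFAIP3 (6.83) positive. REL, CYLD and TNFAIP3 were chosen after their values were seen.

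YAP1 itself had a negative score of -1.96 (adjusted p = 0.0158) and its paralogue WWTR1 a positive score of 1.48 (adjusted p = 0.0443) in the authors' deposited table. The TEAD transcription factors, partners of YAP, went both ways in the authors' deposited table, with TEAD1 (-6.16) and TEAD4 (-5.43) negative and TEAD2 (5.04) and TEAD3 (1.72) positive, and all but TEAD1 were chosen after their values were seen. Of 23 YAP and TAZ target genes, 15 were positive, 6 negative and 2 not past the threshold (median 2.77), and the list was not called (adjusted p = 0.268). The classical targets CTGF (2.51) and CYR61 (4.80) and the tissue factor gene F3 (7.02) were positive in the authors' deposited table, while PTPN14 (-8.55) was negative. Hippo pathway components were positive in 9 and negative in 11 of 21 cases (median -1.96, adjusted p = 0.246), with AMOT at -8.96 and VGLL4 at 5.28 in the authors' deposited table. Whether the NF-κB and YAP target lists differed from each other was not tested. Of 18 super-enhancer readers, cofactors and related genes, 12 were positive and 2 negative (median 3.43, cameraPR adjusted p = 0.0619). MYC (8.92), also a member of the immediate early list, and CDK9 (7.64) were positive and CCNT1 (-7.001) negative in the authors' deposited table. Without MYC, its most extreme member, the list stayed uncalled (cameraPR, adjusted p = 0.130). It was called toward the positive side (adjusted p = 4.73e-03) once GC content and transcript length had been regressed out.

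**Figure D2:**
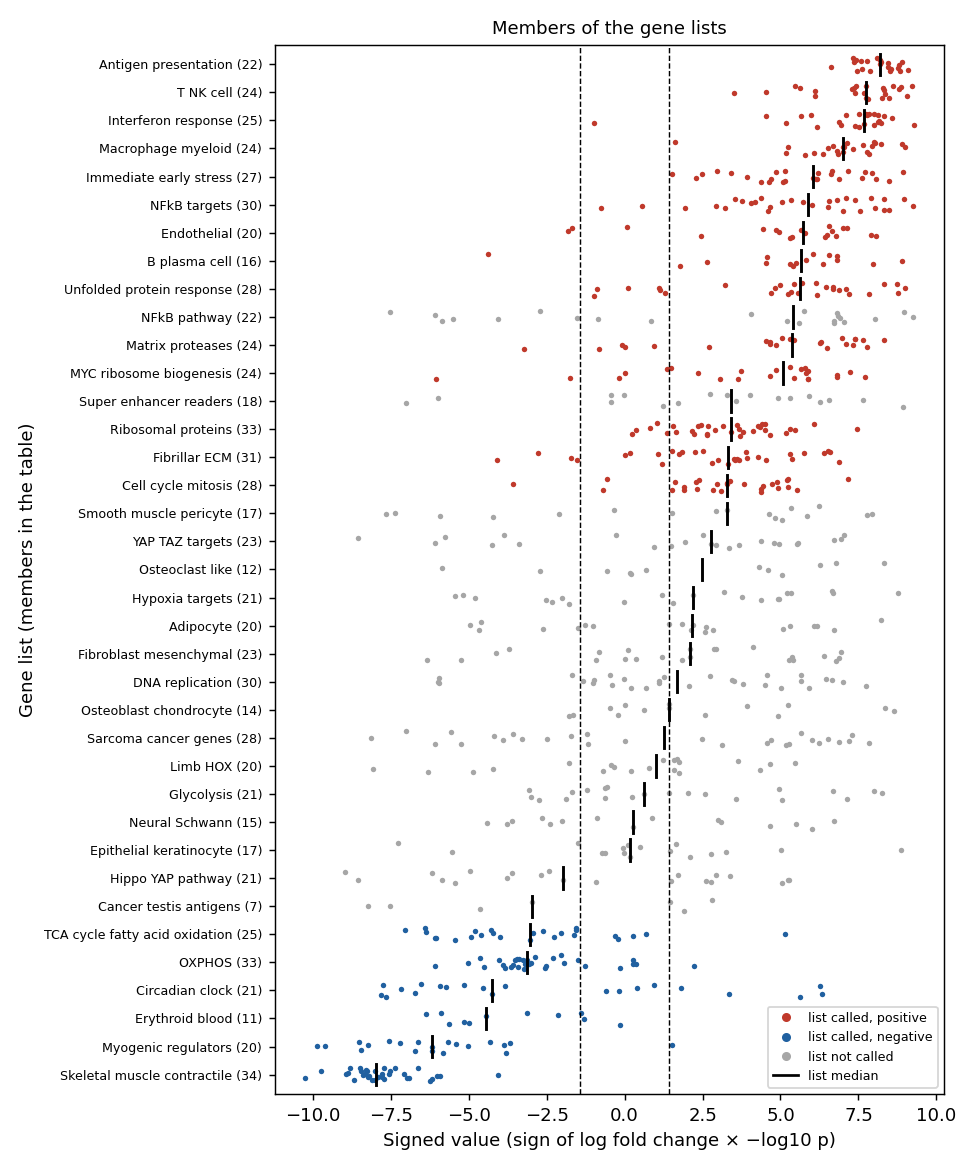
Signed values of the members of 37 of the 38 gene lists, ordered by list median. Each point is 1 gene, the x axis is the sign of the log fold change times −log10 p, black bars are list medians, dashed lines mark the adjusted threshold at 1.43 and colour gives the cameraPR call. Antigen presentation (median 8.20) and the contractile list (median -7.96) lie at the 2 ends, and the YAP and TAZ targets (median 2.77) spread over both sides.

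Proliferation genes leaned to the positive side. Of 28 mitotic genes, 25 were positive and 1 negative (median 3.29, adjusted p = 3.76e-03, or 0.132 with the preset at 0.1). PTTG1 (7.15), PLK1 (5.53) and CDC20 (5.25) led them in the authors' deposited table, and the mitotic transcription factor FOXM1 was the negative member at -3.57. DNA replication genes were positive in 15 and negative in 4 of 30 cases, and that list was not called (adjusted p = 0.146). MCM5 (7.75) and PCNA (6.996) were positive and POLA1 (-6.00) negative in the authors' deposited table. Ribosome biogenesis genes were positive in 19 of 24 cases and negative in 2, with 20 positive when adjusted over the list alone (median 5.09, adjusted p = 8.15e-04, or 0.0683 with the preset at 0.1). Ribosomal proteins were positive in 28 of 33 cases and negative in none (median 3.42, adjusted p = 7.50e-04, or 0.0894 with the preset at 0.1), and their counts depend on how reads shared with pseudogenes were assigned. PES1 (7.72) and FBL (7.22), both of nucleolar ribosome assembly, and RPS16 (7.44) were the leading examples in the authors' deposited table.

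The 28 genes altered in sarcoma or other cancers went both ways, with 14 positive and 11 negative (median 1.26, adjusted p = 0.602). Among them the authors' deposited table gave CDKN2A 7.82, CDK4 7.28, MDM2 -2.50 and the receptor tyrosine kinase gene MET -8.12. RB1 did not pass the threshold, with a score of 0.03 (adjusted p = 0.942) in the authors' deposited table.

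Genes of the unfolded protein response and of the extracellular matrix were mostly positive. The unfolded protein response list had 22 of 28 members positive and none negative (median 5.62, adjusted p = 1.95e-06), led by MANF (9.005), TRIB3 (8.78) and SEC61B (8.74) in the authors' deposited table. Of 24 matrix proteases and their inhibitors, 19 were positive and 1 negative (median 5.36, adjusted p = 4.50e-05), with MMP9 at 8.32, MMP11 at 7.78 and MMP16 at -3.22 in the authors' deposited table. Both of these lists stayed called at a preset of 0.1 (cameraPR, adjusted p = 0.0118 and 0.0215). Fibrillar matrix genes were positive in 23 and negative in 4 of 31 cases (median 3.32, adjusted p = 9.66e-03, or 0.0807 at a preset of 0.05). The most extreme members were the collagen-modifying enzymes PLOD3 (6.86) and LEPRE1 (6.59), and FBN1 (-4.08) for the negative side, in the authors' deposited table. Circadian clock genes were negative in 12 and positive in 5 of 21 cases (median -4.25, adjusted p = 0.0306). PER3 (-7.82), HLF (-7.75) and RORA (-7.64) stood against the repressor NFIL3 (6.33) in the authors' deposited table. The circadian call was lost at a preset of 0.05 (adjusted p = 0.115) and without PER3.

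Several other lists were not called. Hypoxia targets had 12 positive and 7 negative of 21 members (adjusted p = 0.269), with ADM at 8.77 and P4HA1 at -5.44 in the authors' deposited table. Glycolysis genes had 9 positive and 5 negative of 21 (adjusted p = 0.273), with ENO1 at 8.25 and ALDOA at -3.05 there. Fibroblast and mesenchymal markers had 13 positive and 4 negative of 23 (adjusted p = 0.208), with TWIST2 at 6.96 and ZEB1 at -6.33 in the authors' deposited table. Smooth muscle and pericyte markers had 11 positive and 5 negative of 17 (adjusted p = 0.273), with ACTG2 at 7.92 and PLN at -7.63 in the authors' deposited table. Adipocyte markers had 12 positive and 5 negative of 20 (13 positive when adjusted over the list alone; adjusted p = 0.269), with PNPLA2 at 8.23 and LPL at -4.95 in the authors' deposited table. Osteoblast and chondrocyte markers had 7 positive and 2 negative of 14 (6 positive when adjusted over the list alone; adjusted p = 0.186), led by ALPL (8.66) and SPP1 (8.37) in the authors' deposited table. Osteoclast markers had 6 positive and 2 negative of 12 (adjusted p = 0.208), Schwann and neural markers 6 of each sign among 15 (adjusted p = 0.842), and limb HOX and related genes 9 positive and 5 negative of 20 (adjusted p = 0.913). The limb list had a positive median (1.01) while its rank test pointed to the negative side. Epithelial markers had 7 positive and 3 negative of 17 (6 and 2 when adjusted over the list alone; adjusted p = 0.849), with KRT14 at 8.88 and TP63 at -7.25 in the authors' deposited table. Of the 7 cancer-testis genes tested, 3 were positive and 4 negative (adjusted p = 0.208), with CTCFL at -8.23 and MAGEA10 at -7.53 in the authors' deposited table.

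The sign of a gene went with its base composition. Across 17742 genes the score had a Spearman correlation of 0.433 with the GC content of the longest transcript and of -0.214 with its length. This correlation is across genes, which are not independent replicates. Among genes past the threshold, 21.8% were positive in the tenth of genes with the lowest GC content and 87.8% in the tenth with the highest. GC content and length together accounted for 21.3% of the variance of the signed z-values. All 21 called lists kept their call and direction when both were regressed out, an alternative chosen after seeing the data.

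**Figure D3:**
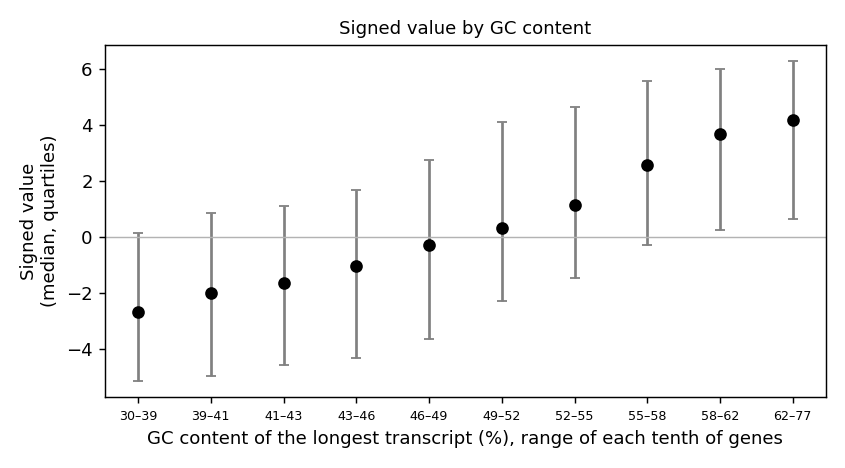
Signed value against GC content of the longest transcript, over 10 groups of equal size from 17742 genes. Points are medians and bars run from the lower to the upper quartile. The median rises from -2.68 in the group with the lowest GC content to 4.17 in that with the highest.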

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

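The regression on GC content and length was chosen after seeing the data. A Bonferroni adjustment left 2697 positive and 1960 negative genes in place of 7176 and 6334, by its stricter construction. Thresholds of 0.01 and 0.001, the Benjamini-Yekutieli adjustment and the removal of non-coding and uncharacterised names kept both counts within 1.5 times. Of the 21 called lists, 12 kept call and direction under all 9 alternatives. With the correlation between genes preset at 0.1, 2 lists were called toward the negative side in place of 6, and 10 in place of 15 toward the positive side. Among the 9 lists lost there were those of mitosis, circadian clock, erythroid, fibrillar matrix, ribosome biogenesis, oxidative phosphorylation, ribosomal proteins, and citric acid cycle with fatty acid oxidation. A preset of 0.05 lost 3 of these, GSEA lost 1, and leaving out the most extreme member lost 2, the circadian list among them. The NF-κB pathway list was gained by GSEA and by the random-list comparison, and stayed uncalled under the other alternatives. The NF-κB target list stayed called (adjusted p at most 4.55e-03) and the YAP and TAZ target list stayed uncalled (adjusted p 0.124 to 0.543) under every alternative. Direction turned in uncalled lists only, where the cause was not tested. These were glycolysis with GC content and length regressed out (adjusted p = 0.822), Schwann and neural markers without the most extreme member (0.917), and epithelial markers against random lists (0.952), without the most extreme member (0.884) and with GC content and length regressed out (0.695). The limb HOX list turned positive with z-values (0.902), against random lists (0.532) and without the most extreme member (0.851). No paired analysis was possible because the table holds no values per library and the labels give a single group, and for the same reason no library could be left out and no regrouping of libraries could be counted. Depth, fold changes and the contribution of any one library are unknown.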

Other observations

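Families of genes defined by a shared symbol stem were tested after the data had been seen, with the same list test, over 23 families. The 2 tests of the GC trend that use zinc finger genes and the genes outside the lists had their outcomes stated before they were run, and all other tests below were chosen after the result was seen. Several immune families were positive. All 8 GIMAP genes, GTPases of lymphocyte survival, were positive (median 6.17, adjusted p = 7.55e-04), as were 30 of 40 chemokine ligands (3 negative, median 4.96, adjusted p = 2.91e-05), 27 of 33 TNF ligands and receptors (3 negative, median 5.53, adjusted p = 5.44e-05) and 9 of 10 Toll-like receptors (median 3.80, adjusted p = 0.0311). With the correlation preset at 0.1, the GIMAP call held (adjusted p = 0.0297), while the chemokine (0.0669), TNF (0.0669) and Toll-like receptor (0.241) calls were lost. HLA genes (20 of 24 positive, 1 negative, adjusted p = 1.16e-06) and interleukin receptors (24 positive and 10 negative of 41, adjusted p = 0.0234) were called too, and at the preset of 0.1 the HLA call held (adjusted p = 0.0175) and the interleukin receptor call was lost (0.309). Cathepsins, lysosomal proteases, were positive in 12 of 15 cases and negative in 1 (adjusted p = 1.73e-03), and proteasome subunits in 29 of 44 cases and negative in 5 (adjusted p = 0.0122), and both calls were lost at that preset (adjusted p = 0.0669 and 0.309). Some members also belong to the lists fixed in advance, 12 of the HLA genes, 7 chemokines, 4 TNF family genes, 3 cathepsins, 3 proteasome subunits and 1 interleukin receptor. Without them these 6 families were still called, with adjusted p from 5.34e-04 for the chemokines to 0.0428 for the proteasome.

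On the negative side stood 315 of 565 genes with a zinc finger symbol (ZNF, ZFP, ZKSCAN or ZSCAN), against 102 positive (median -2.32, adjusted p = 5.83e-06). Kelch-like genes were negative in 27 and positive in 11 of 45 cases (adjusted p = 7.43e-03), and protocadherins, neural adhesion molecules, in 36 and 9 of 65 (adjusted p = 0.0122). With the correlation preset at 0.1, the zinc finger (adjusted p = 0.282), Kelch-like (0.282) and protocadherin (0.309) calls were lost. Of the 23 families 12 were not called, among them mitochondrial ribosomal proteins, with 31 positive and 28 negative of 79 (adjusted p = 0.944), and Sec translocation and coat genes, with 26 positive and 13 negative of 47 (adjusted p = 0.0837). With GC content and length regressed out, 4 of these 12 were called, the guanylate-binding proteins (adjusted p = 0.00901), the Sec and coat genes (0.0221), the potassium channels toward the negative side (0.0304) and the vacuolar ATPase subunits (0.0490), and the 11 families called before kept their call and direction.

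The first pattern weighed is the trend with GC content over all genes. The listed genes and families by themselves do not account for it. Their programmes as a whole are not excluded, because genes of them that no list names remain in the test. The correlation was 0.4402 over the 15597 genes outside all lists and families, against 0.433 over all genes. Within the genes with a zinc finger symbol it was 0.4937 (563 genes, 95% bootstrap interval over genes 0.425 to 0.562), which restates the trend in a subset of the genes and does not decide where it comes from. A difference in GC-dependent recovery between the libraries on the 2 sides, such as another library preparation or RNA quality, stays open, as does regulation that follows base composition. The trend is not the whole cause of the list calls, as 21 of 21 kept call and direction with GC content and length regressed out. Single genes and lists near the threshold stay open, because any batch between the sides cannot be told apart from the contrast.

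The second pattern is the block of muscle genes at the negative end. GC content and length do not account for the block (adjusted p = 2.3628e-14 after regression). A lower share of muscle fibres on the positive side could raise every other cell type, yet erythroid genes were not raised. The highest erythroid score (-0.1614) lay below the lowest macrophage score (1.61). Schwann and neural markers, with 6 of each sign among 15, were not raised as a list either (cameraPR, adjusted p = 0.842). Nor were epithelial markers, with 7 positive and 3 negative of 17 (cameraPR, adjusted p = 0.849). Endothelial markers were raised, with 17 of 20 positive. These values do not decide whether that lower share is the whole reason for the positive leukocyte lists. The content of blood and of each other cell type may differ separately. Whether the negative side holds skeletal muscle tissue stays open, because the labels name no comparator and the count of 34 negative contractile members of 34 restates the pattern. Proliferating cultured myoblasts as the negative side are not excluded by the 25 positive mitotic members of 28. A positive side that divided faster would give the same sign, and the mitotic call was lost at a preset of 0.1 (cameraPR, adjusted p = 0.132). Erythroid genes argue against a negative side of cultured cells alone, which would hold no blood. Of 11 erythroid genes 8 were negative and none positive, though that list was not called at a preset of 0.1 (cameraPR, adjusted p = 0.0641). The contractile list, with adult myosin heavy chains among its members, was negative in 34 of 34 cases (median -7.96). This argues against proliferating myoblasts alone, which have not formed fibres. The 19 negative of 20 myogenic genes could come from myoblasts or from muscle tissue. Another tissue with striated muscle, and blood content as a separate difference, stay open beside skeletal muscle tissue.

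The third pattern is the positive NF-κB target list. GC content and length do not account for its call (adjusted p = 4.8998e-08 after regression). Infiltrating leukocytes may carry part of it, as 48 of 48 T, NK and macrophage markers were positive, and so may the handling of tissue before extraction, as 27 of 27 immediate early genes were positive. Neither can be told apart from signalling in tumour cells, because the table has no values per library or cell type and the labels give no handling times. Signalling in the tumour cells themselves stays among the open explanations, untested. It would apply only if the positive side is the tumour, which the labels do not say.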
